A study of Mus musculus with 14 samples.

How the data were processed

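RNA from the rostral cortex of newborn mice was sequenced after polyA selection with an Illumina TruSeq kit, per the labels' protocols, in 4 wild type C57BL/6J and 4 Auts2 cKO animals. For the pull-down, total RNA from cortex was immunoprecipitated with a Magna-RIP kit and made into libraries with a SMARTer stranded kit, per the labels' protocols, in 2 trios of AUTS2 RIP, IgG and 10% input. Libraries of floxed animals without Cre, or of animals with Cre alone, were not analysed here.

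The deposited values are FPKM per transcript, fragments scaled by transcript length and library size, per the file headers. The submitters' processing notes name STAR 2.5, SAMtools, Cuffdiff 2.2.1 and the genome build GRCm38.p4 (mm10), and the file headers name GENCODE vM14 transcripts. Filters, strand settings and library scaling are not given in the sources used here. Each of the 3 tables was scaled by itself: the AUTS2 RIP libraries in the table with IgG and in the table with input differed by a single factor, 1.018 for A and 1.015 for B. Tests therefore stay within a table. Each table held 128508 transcripts, of which 127975 matched GENCODE vM21 by identifier and 533 did not. The lowest share of a library's FPKM carried by matched transcripts was 99.475%.

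The tables hold no counts, and low FPKM values of an isoform-based estimate give no whole reads, so the depth and its counting error are unknown. The libraries' summed FPKM ran from 282029 to 340979. The top 10 genes took 3.60% to 4.13% of it in frontal cortex, 5.74% and 5.92% in the RIP, 9.50% and 8.13% in the IgG and 13.0% and 13.8% in the input libraries. An exact 0 can be a failed estimate. Tubb3, an abundant neuronal tubulin, was listed at 0 in all 8 frontal cortex libraries and at 256 to 354 FPKM in the pull-down tables. None of the 37 mitochondrial genes listed stood above 1 FPKM. Genes listed at 0 in some libraries of a table and above 10 FPKM on average in the others numbered 0, 17 and 38 in the frontal cortex, IgG and input tables. No libraries were identical. The labels call the libraries biological replicates. Library cKO 4 was matched to its values by library number, as its label and its column give it different short names, so statements on cKO 4 alone rest on that match.

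Transcripts were summed per gene symbol. Genes with a mean FPKM of at least 1 in a comparison were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust empirical Bayes, two-sided, and with Benjamini-Hochberg adjustment at 0.05. Fold changes are on that log2 scale and understate the change of low genes. The 46 gene lists were tested with camera at a preset correlation of 0.01, adjusted over lists with at least 5 tested genes, with an estimated correlation and with fry beside it. With fry 0, 7 and 11 lists passed in the cKO, IgG and input comparisons. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and figures. Samples, tests, lists and most alternatives were fixed before the data were examined.

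The named genes are Auts2 and Emx1 in each comparison, the 8 largest rises and 8 largest falls among called genes without overlap between groups and with at least 2 FPKM in the higher group, and up to 4 members with the smallest p of each list past its threshold. Some genes that this rule selects are not reported here. Of other lists at most 2 members are named, and with under 5 called genes the 5 highest and 5 lowest test statistics are given as values. Symbols of the form Gm plus a number, Rik clones and symbols with the ending -ps were left out of the ranking, 82 higher and 481 lower genes against IgG and 129 and 488 against input. Xist, used for its state, and the genes of the sterol and imprinted lists were chosen after their values were seen, and Tubb3 for its value of 0.

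The fits were tested on simulated data with 12786, 14570 and 14458 genes as in the cKO, IgG and input comparisons. Noise was normal and independent between genes and libraries, with each gene's fitted variance, and 100 genes were changed at each fold. In the cKO design 90% of genes changed 1.5-fold and 99.8% of those changed 2-fold were called, and 4.9% of calls were false. In the IgG design 50.8% of 2-fold and 85.2% of 4-fold changes were called with 13.5% of calls false, and in the input design 49.6% and 82.6% with 11.4% false. With 2 libraries per group the share of false calls in these simulations is thus above the nominal 5%. Real libraries can resemble each other or stand apart, and the numbers of changed genes differ, so these shares need not carry over.

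The series design calls the RIP, IgG and input libraries matched trios, with the letters A and B. The deviations of same-lettered libraries from their group means correlated at r = 0.0088 for RIP and IgG and 0.012 for RIP and input.

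Alternatives were a pseudocount of 0.1 or 5, no filter or a mean of at least 5 FPKM, median-ratio rescaling, quantile normalization, limma without trend and robust settings, a replicate block, a threshold of 0.1, transcripts in place of genes, and each library left out in turn. Added after the data were seen were Xist state as a covariate (Xist above 10 FPKM), removal of genes listed at 0 in some libraries, removal of each library's length and GC trend by splines with 5 degrees of freedom, the rescalings of the list tests, the estimated correlation for the pulled-down genes in the cKO, the test of the AUTS2 partner list without Auts2, and the overlap of pulled-down genes with each direction of change in the cKO.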

Results

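RNA abundance was measured by sequencing in the neonatal mouse cortex, in 14 libraries from postnatal day 0.5. The frontal cortex set held 4 wild type and 4 Auts2 conditional knockout (cKO) libraries. In the cKO, exon 15 of Auts2, an autism-associated gene whose protein acts in transcription and in the cytoplasm, was flanked by loxP sites. The Cre recombinase was expressed from Emx1, a gene active in the progenitors of cortical excitatory neurons. The RNA immunoprecipitation (RIP) set held 2 libraries pulled down from wild type cortex with an antibody against the C terminus of AUTS2, 2 pulled down with control IgG and 2 of the 10% input, in matched trios A and B. For each of these libraries 2 pooled neonates are given. Values are FPKM summed over the transcripts of a gene. Read counts are not given, so the depth of each library is unknown and no counting interval can be set. Wild type and cKO libraries held 60668 to 63043 transcripts above 0, the RIP libraries 56312 to 57726, the IgG libraries 46739 and 52158, and the input libraries 44946 and 46758.

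Auts2 RNA was lower in every cKO library than in every wild type library. The wild type values were 87.7, 92.2, 55.9 and 60.2 FPKM and the cKO values 29.8, 35.2, 30.4 and 34.5 FPKM. The means were 74.0 ± 18.6 and 32.5 ± 2.77 FPKM (SD, n = 4 each), a log2 fold change of -1.13 (SE 0.14, adjusted p = 0.0237, limma). Auts2 (ENSMUSG00000029673.17) lies on chromosome 5, positions 131437333 to 132543344 of GRCm38, on the minus strand. Counted along the 19-exon transcript ENSMUST00000161226, exon 15 is a 142 bp exon at 131451884 to 131452025. The 9 transcripts that contain it summed to 72.0 ± 18.1 FPKM in wild type and 30.6 ± 2.40 FPKM in the cKO, 42.5% of the wild type mean. The 11 transcripts without it summed to 1.96 ± 0.63 and 1.85 ± 0.51 FPKM. These are estimates over whole annotated transcripts, so they measure neither the reads of exon 15 itself nor the share of RNA that kept it. Emx1 (chromosome 6, 85187438 to 85204462), the gene that drives Cre, stood at 10.5 ± 1.72 FPKM in wild type and 8.06 ± 0.54 FPKM in the cKO (log2 -0.33, adjusted p = 0.628, limma).

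Besides Auts2, Ndn rose and S100a10 fell in the cKO, which was compared with wild type to ask which transcripts depend on Auts2 in the newborn frontal cortex. Ndn encodes necdin, a growth suppressor of postmitotic neurons expressed from the paternal allele. It stood at 94.0 ± 8.88 FPKM in the cKO and 54.1 ± 2.09 FPKM in wild type (n = 4 each), a log2 fold change of 0.78 (SE 0.07, adjusted p = 0.0015, limma). S100a10 encodes p11, the partner of annexin A2. It stood at 50.7 ± 1.19 against 74.5 ± 7.05 FPKM, a log2 fold change of -0.54 (SE 0.07, adjusted p = 0.0237, limma). Ndn lies on chromosome 7 at 62346569 to 62350262, where Gm32061 is annotated on the opposite strand, and S100a10 on chromosome 3 at 93555080 to 93564643. For neither gene did the values of the groups overlap.

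These 3 genes, 1 higher and 2 lower, were the calls among 12786 genes tested. An unadjusted p under 0.05 (limma) was found for 1011 genes, where 639 would have it by chance. That count depended on single libraries: it was 489 and 478 without wild type 1 or 2, under the number by chance. It was 1527 and 1601 without wild type 3 or 4, and 744 to 1079 without a cKO library. In 4.41% of genes the groups did not overlap, against 2.86% by chance. The next genes by test statistic did not pass and are given as values. Penk, the enkephalin precursor of striatal neurons, stood at 7.01 ± 2.30 FPKM in the cKO and 2.5 ± 0.38 FPKM in wild type (adjusted p = 0.0867, limma). BC051226 stood at 8.64 ± 0.61 and 5.58 ± 0.29 FPKM, the homeobox gene Tshz2 at 6.29 ± 1.01 and 3.54 ± 0.33 FPKM, and Mmab, an enzyme of cobalamin metabolism, at 9.26 ± 0.27 and 6.60 ± 0.60 FPKM. On the other side were Cyp26b1, which degrades retinoic acid, at 5.38 ± 1.08 and 9.68 ± 1.28 FPKM, Echdc2 at 7.38 ± 0.57 and 10.3 ± 0.82 FPKM, and the potassium-chloride cotransporter Slc12a7 at 2.34 ± 0.27 and 3.67 ± 0.33 FPKM. Cyp26b1 lies within 20 Mb of Emx1 and Mmab within 20 Mb of Auts2, the engineered loci. Cyp26b1, at 84571414 to 84593908 of chromosome 6, is by far the nearer to its locus (Emx1 starts at 85187438). Mmab is at 114431034 to 114444060 of chromosome 5, where Auts2 starts at 131437333.

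Wild type 1 and 2 were closer to each other (r = 0.993 across genes, which are not independent replicates) than to any other library (0.980 to 0.987), cKO 1 stood at 0.980 to 0.986 from all others, and the other 5 libraries at 0.992 to 0.994 from each other. Auts2 was highest in wild type 1 and 2. Ndn was called in every fit tried, while the calls of Auts2 and S100a10 depended on single libraries. The adjusted p of Auts2 was 0.0659 and 0.0593 without wild type 1 or 2, and 0.0793, 0.0886, 0.113 and 0.123 without cKO 1, 2, 3 or 4, with log2 fold changes between -1.02 and -1.26 over all 8 omissions. That of S100a10 was 0.142 and 0.0859 without wild type 2 or 3, and 0.176, 0.124 and 0.147 without cKO 2, 3 or 4. The count of called genes was 1 without wild type 2 or cKO 2, 3 or 4. The log2 fold change of S100a10 stayed between -0.49 and -0.59 over these omissions. Xist, the RNA of the inactive X chromosome, stood at 217 FPKM in wild type 2 and at 212, 214 and 250 FPKM in cKO 1, 2 and 3, and at most at 0.40 FPKM in the other 4 libraries. With Xist state as a covariate the adjusted p of Ndn was 0.025, of Auts2 0.0706 and of S100a10 0.103, and 1 gene was called.

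**Figure D1:**
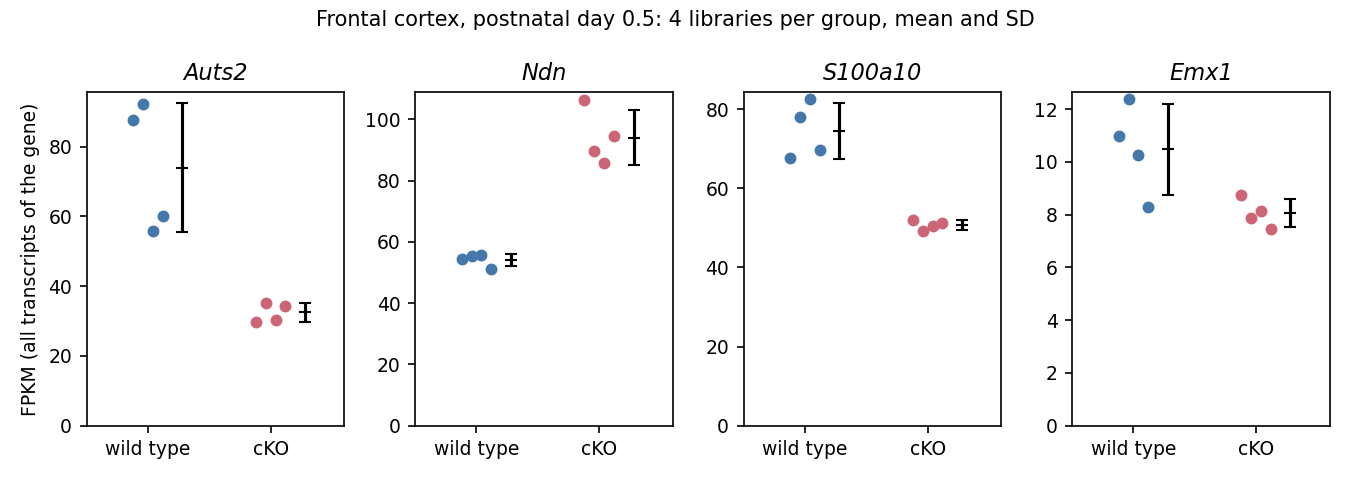
FPKM of Auts2, Ndn, S100a10 and Emx1 in the 4 wild type (blue) and 4 cKO (red) frontal cortex libraries, each point a library, with the mean and SD beside them. The groups do not overlap for Auts2, Ndn and S100a10, with Auts2 at 74.0 and 32.5 FPKM on average.

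Of 38 gene lists tested, 6 shifted in the cKO with the preset correlation of camera, and none with an estimated correlation. Nuclear-encoded genes of oxidative phosphorylation stood higher: 73 of 75 had a positive fold change, with a median log2 of 0.09, although 0 passed alone. Examples are the complex I subunit Ndufa6, at 52.4 ± 5.21 FPKM in the cKO and 43.0 ± 1.66 FPKM in wild type, and Uqcr11 of complex III, at 75.2 ± 8.97 and 64.9 ± 2.81 FPKM. The list's adjusted p was 4.9e-10 (camera, limma), and the adjusted p = 0.946 with an estimated correlation. Its mean log2 level was 5.90 to 5.97 in wild type. In cKO 2 and 3 it was 5.95 and 5.97, within that range, and in cKO 4 and 1 it was 6.03 and 6.20. Zinc finger genes named Zfp stood lower, with 72 of 325 positive and a median log2 of -0.09, such as Zfp646 at 9.58 ± 1.35 and 12.1 ± 1.39 FPKM. The members with the smallest p were on the other side, Zfp277 at 9.89 ± 0.63 and 7.82 ± 0.89 FPKM and Zfp536 at 7.98 ± 1.49 and 5.67 ± 0.98 FPKM. The adjusted p was 4.5e-06, and adjusted p = 0.946 with an estimated correlation. Of both lists 0 members passed, over all genes or adjusted over the list alone. Without cKO 4 the median of the Zfp genes was -0.04 (adjusted p = 0.0287), and without wild type 1 it was -0.06. The groups overlapped in the mean log2 level of the Zfp genes, at 2.99 to 3.15 in wild type and 2.87 to 3.08 in the cKO.

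Intermediate progenitor genes, which mark the dividing precursors of excitatory neurons, stood lower, with 0 of 12 positive and a median log2 of -0.11. Over all genes 0 passed, and adjusted over the list alone 2 fell. These were the proneural factor Neurog2, at 1.88 ± 0.47 FPKM in the cKO and 2.83 ± 0.37 FPKM in wild type, and the rhomboid family gene Rhbdl3, at 1.83 ± 0.21 and 2.58 ± 0.29 FPKM. The list's adjusted p was 0.0023 (camera, limma), and adjusted p = 0.852 with an estimated correlation. Its median was -0.05 without cKO 3 (adjusted p = 0.0201), -0.17 without wild type 4 and -0.23 without cKO 1. The mean log2 level of the list was 2.59 to 2.87 in wild type, 2.69 in cKO 1 and 2.43 to 2.52 in the other cKO libraries. Nuclear-retained long non-coding RNAs stood higher, with 11 of 15 positive and a median log2 of 0.21 (adjusted p = 0.0106, and adjusted p = 0.852 with an estimated correlation). Over all genes 0 of them passed, and adjusted over the list alone 1 rose, the imprinted Rian, at 513 ± 13.8 and 404 ± 60.8 FPKM. With the Xist covariate the median was 0.20 (adjusted p = 0.0036). The list holds Xist, and its mean log2 level was 4.64 in cKO 4, the cKO library low in Xist, against 5.11 to 5.17 in the other cKO libraries. The median was 0.12 without wild type 1 or 2 and 0.14 without cKO 3.

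Cytosolic ribosomal protein genes had 78 of 85 positive fold changes and a median log2 of 0.05 (adjusted p = 0.0128, and adjusted p = 0.946 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. Their mean log2 level was 8.01 in cKO 1 and 7.68 to 7.76 in the other cKO libraries. Without cKO 1 the median was -0.02 and the list was called lower (adjusted p = 0.0312). Without wild type 3 or 4 its adjusted p was 0.226 and 0.568, with the Xist covariate 0.733, and under quantile normalization the median was -0.0004. The median of the oxidative phosphorylation list was 0.05 without cKO 1 (adjusted p = 0.0039). The list of AUTS2 and its polycomb partners had 5 of 14 positive and a median log2 of -0.07 (adjusted p = 0.0359, and adjusted p = 0.852 with an estimated correlation). Only Auts2 fell in it, over all genes and adjusted over the list alone, and the acetyltransferase Ep300 stood at 15.5 ± 3.03 and 18.1 ± 1.73 FPKM. The list holds the deleted gene, so its shift is in part set by the design: for the 13 other members camera gave p = 0.067, and p = 0.208 with an estimated correlation. The whole list's adjusted p was 0.0957 without wild type 3, 0.136 without cKO 1 and 0.0766 with the Xist covariate, and its median was -0.03 without wild type 2 and -0.02 without cKO 1. The count of lists was 12 without cKO 1 and 11 without cKO 3.

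Lists for other cell types were tested for a change in tissue makeup, and those for radial glia, deep-layer neurons, interneurons, astrocytes, microglia, endothelium and red blood cells did not pass, with adjusted p = 0.244 for interneurons and 0.277 for microglia and red blood cells (camera, limma). Closer to the threshold were upper-layer neurons, with 3 of 15 positive (adjusted p = 0.174), and proliferation genes, with 6 of 24 positive (adjusted p = 0.0524). A list of Wnt, Bmp and Shh pathway genes, not a cell type list, had 4 of 15 positive and a median log2 of -0.12. Its adjusted p was 0.0524 (camera, limma), and adjusted p = 0.852 with an estimated correlation. The mean log2 level of the proliferation list was 2.72 to 2.78 in cKO 2, 3 and 4, 2.90 to 2.97 in wild type and 3.15 in cKO 1. Of the striatum list 7 of 11 members were positive, and adjusted over the list alone 1 rose, Penk (list adjusted p = 0.286). The mean log2 level of the striatum list was 2.54 in cKO 4 and 1.90 to 2.06 in the other 7 libraries.

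In the pull-down, Ryr1, Trank1, Mdn1 and Ryr3 stood above the IgG control and Igf2, Spaca6 and Selenot below it, in the comparison that asks which transcripts the AUTS2 antibody brings down beyond the background of a control antibody. Of the genes with the largest rises, Ryr1, a calcium release channel of the endoplasmic reticulum, stood at 39.9 ± 2.77 FPKM in the RIP and 7.28 ± 0.98 FPKM in the IgG libraries (n = 2 each), a log2 fold change of 2.31 (SE 0.16). Its most abundant transcript is a short one of 1028 bases. Trank1 stood at 276 ± 3.90 and 70.7 ± 9.99 FPKM (log2 1.96, SE 0.12). The ribosome assembly factor Mdn1 stood at 62.6 ± 0.55 and 16.2 ± 1.47 FPKM, and the channel Ryr3 at 72.7 ± 2.05 and 19.3 ± 4.92 FPKM. The adjusted p of these 4 genes was between 0.0025 and 0.0030 (limma). The axonemal dynein Dnah7a stood at 3.40 and 2.84 FPKM in the RIP libraries and at 0 and 0.11 FPKM in the IgG libraries. The small nucleolar RNAs Snora7a, at 1.71 and 4.64 FPKM, and Snord68, at 2.76 and 2.85 FPKM, were listed at 0 in both IgG libraries.

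Among the largest falls was Igf2, an imprinted growth factor, at 2.05 ± 0.66 FPKM in the RIP and 22.8 ± 1.44 FPKM in the IgG libraries, a log2 fold change of -2.98 (SE 0.23, adjusted p = 0.0025, limma). Spaca6, whose locus holds Mir125a, Mir99b and Mirlet7e, stood at 14.6 ± 0.46 and 108 ± 12.5 FPKM (log2 -2.80, SE 0.13). The nucleolar RNA Snora23 stood at 7.94 ± 3.85 and 64.8 ± 11.9 FPKM, the vault RNA Vaultrc5 at 3.41 ± 2.45 and 24.8 ± 9.40 FPKM, and the selenoprotein gene Selenot at 6.04 ± 1.67 and 39.1 ± 4.98 FPKM. Cox6c2, annotated as a processed pseudogene and a near copy of Cox6c, whose reads cannot be told from it with certainty, stood at 0 and 2.12 FPKM against 11.2 and 5.84 FPKM. Cmss1 and Filip1l, which overlap on opposite strands, were listed at 0 in both RIP libraries, with 12.6 and 8.22 FPKM of Cmss1 and 5.81 and 4.05 FPKM of Filip1l in the IgG libraries. Trank1, Mdn1, Selenot and Vaultrc5 overlap no other annotated gene, while Ryr1, Ryr3, Igf2 and Spaca6 overlap at least 1, and Snora7a, Snord68 and Snora23 lie inside other genes. Whether the counting used strand is not given in the sources used here, which leaves the values of overlapping genes uncertain. Auts2 itself stood at 275 ± 0.14 FPKM in the RIP and 237 ± 3.69 FPKM in the IgG libraries (log2 0.21, adjusted p = 0.133; log2 -0.25 with length and GC trends removed), and Emx1 at 5.48 ± 0.12 and 7.10 ± 1.59 FPKM (log2 -0.31, adjusted p = 0.372).

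In all, 3406 of 14570 genes passed against IgG, 1994 higher and 1412 lower, of which 1922 and 906 were protein-coding. The balance of directions depends on scaling, with 1367 higher and 1349 lower under quantile normalization, 1766 and 1522 under median-ratio rescaling, and 942 and 934 without trend and robust settings. Unadjusted p was under 0.05 for 5546 genes, and the groups did not overlap for 64.4% of genes, against 33.3% by chance. With any of the 4 libraries left out, its group kept a single library and fewer genes were called. The calls thus need all 4 libraries. Such a fit has fewer degrees of freedom, so the fall cannot show whether the calls rest on a particular library. With no model, 439 genes were at least 2-fold higher and 721 at least 2-fold lower in both trios, where independent trios would give 75.5 and 139. The balance depends on low genes: with a mean of at least 5 FPKM these were 352 and 302.

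Of 31 mRNAs known as targets of FMRP, the fragile X protein that binds brain mRNAs, 25 rose, 0 fell and 6 did not pass against IgG, with a median log2 of 0.99. Adjusted over the list alone, 27 rose and 2 fell. The ubiquitin ligase Mycbp2 stood at 215 ± 9.03 against 67.2 ± 6.11 FPKM and the cytoskeletal linker Macf1 at 482 ± 32.5 against 193 ± 11.1 FPKM. The list's adjusted p was 8.4e-12 (camera, limma), and adjusted p = 0.560 with an estimated correlation. With length and GC trends removed its median was 0.40 (adjusted p = 6.2e-05). Of 35 autism risk genes, 17 rose and 3 fell, and adjusted over the list alone 18 rose and 4 fell. Among them were the chromatin remodeller Chd8, at 121 ± 2.30 against 50.5 ± 0.87 FPKM, and the histone methyltransferase Kmt2a, at 206 ± 5.36 against 77.6 ± 11.5 FPKM (adjusted p = 0.00037, and adjusted p = 0.560 with an estimated correlation). Of 35 mRNAs for nuclear RNA-binding and splicing proteins, 18 rose and 2 fell, and adjusted over the list alone 19 rose and 2 fell. The splicing factors Luc7l3, at 335 ± 20 against 125 ± 4.74 FPKM, and Srrm2, at 559 ± 5.11 against 231 ± 21.6 FPKM, were among them (adjusted p = 2.2e-05, and adjusted p = 0.691 with an estimated correlation). Of 60 replication-dependent histone genes, 14 rose and 0 fell, over all genes and adjusted over the list alone, with Hist1h1e at 1271 ± 93.6 against 570 ± 40.7 FPKM (adjusted p = 0.0041, and adjusted p = 0.704 with an estimated correlation).

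Small structured RNAs stood lower in the pull-down than in IgG. Of 16 small non-coding RNAs chosen by symbol, which are spliceosomal, 7SK and RNase P or MRP RNAs and also signal recognition particle, vault, Y, telomerase and U3 RNAs, 11 fell and 1 rose, and adjusted over the list alone 14 fell and 1 rose. The transcription elongation regulator Rn7sk stood at 2066 ± 92.1 against 3956 ± 127 FPKM and Rpph1, the RNA of RNase P, at 149 ± 58.2 against 595 ± 14.9 FPKM (adjusted p = 1.1e-05, and adjusted p = 0.691 with an estimated correlation). Of 83 small nucleolar and Cajal body RNAs, 22 fell and 3 rose, over all genes and adjusted over the list alone, with Snora81 at 53.2 ± 2.41 against 109 ± 5.31 FPKM (adjusted p = 6.9e-05, and adjusted p = 0.606 with an estimated correlation). Of 17 nuclear-retained long non-coding RNAs, 7 fell and 1 rose, and adjusted over the list alone 10 fell and 1 rose. Gm26917 stood at 49.7 ± 16.2 against 572 ± 44.2 FPKM and Dlx6os1 at 6.82 ± 0.18 against 34.3 ± 1.49 FPKM (adjusted p = 0.00037, and adjusted p = 0.560 with an estimated correlation).

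Some neuronal mRNAs stood lower as well. Of 13 GABA receptor genes, 6 fell and 1 rose, over all genes and adjusted over the list alone, with the subunit Gabrb2 at 13.4 ± 0.84 against 34.5 ± 1.11 FPKM (adjusted p = 0.0021, and adjusted p = 0.560 with an estimated correlation). Of 29 neuronal RNA-binding proteins, 12 fell and 2 rose, and adjusted over the list alone 15 fell and 4 rose. The Hu protein gene Elavl2 stood at 10.4 ± 0.10 against 26.6 ± 0.39 FPKM and the Musashi gene Msi2 at 19.5 ± 3.36 against 47.1 ± 4.2 FPKM (adjusted p = 0.0061, and adjusted p = 0.560 with an estimated correlation). These were 9 of 41 lists, and 0 passed with an estimated correlation. Under quantile normalization the adjusted p was 0.115 for the nuclear RNA-binding proteins and 0.199 for the autism genes, and with length and GC trends removed it was 0.166 for the autism genes and 0.162 for the small nucleolar RNAs, and the median of the GABA receptors went from -0.66 to -0.30.

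Against input, the comparison that sets the pulled-down RNA beside the starting RNA, Ryr1, Flna and Unc80 rose, and the RNA of the signal recognition particle, Rny1 and Rpph1 fell. Ryr1 stood at 40.5 ± 2.73 FPKM in the RIP and 5.17 ± 2.26 FPKM in the input libraries (n = 2 each, log2 2.80, SE 0.27). The actin crosslinker Flna stood at 289 ± 5.56 and 50.7 ± 8.92 FPKM (log2 2.5, SE 0.13), and Unc80, a subunit of the sodium leak channel, at 37.0 ± 2.21 and 5.71 ± 0.05 FPKM. Neb, the giant actin-binding protein of muscle, stood at 37.2 ± 1.89 and 6.14 ± 3.27 FPKM, and Tchh at 17.5 ± 1.13 and 2.17 ± 0.09 FPKM. The adjusted p of these 5 genes was between 0.00068 and 0.0032 (limma). Snora9, at 7.80 and 2.94 FPKM, and Snord88a, at 8.14 and 2.73 FPKM in the RIP libraries, were listed at 0 in both input libraries. Flna overlaps no other annotated gene, and the others of these overlap at least 1.

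The RNA of the signal recognition particle, listed as Rn7s1, Rn7s2 and Rn7s6, had the largest falls. Its near-identical copies stood at 37.5 ± 19.7 against 1443 ± 143 FPKM, 65.6 ± 44.5 against 2263 ± 136 FPKM and 20.9 ± 17.6 against 768 ± 67.1 FPKM, and how reads were split between them is uncertain. The Y RNA Rny1 stood at 67.4 ± 39.8 against 1555 ± 208 FPKM, Vaultrc5 at 3.46 ± 2.48 against 84.8 ± 8.11 FPKM, and Rpph1 at 152 ± 58.9 against 3071 ± 529 FPKM, log2 fold changes of -4.63, -4.38 and -4.37 with adjusted p of at most 0.0013 (limma). Snord7, at 5.83 and 22.2 FPKM, and Snord35b, at 12.6 and 7.83 FPKM in the input libraries, were listed at 0 in both RIP libraries. Auts2 stood at 279 ± 0.42 FPKM in the RIP and 162 ± 32.3 FPKM in the input libraries (log2 0.80, SE 0.14, adjusted p = 0.0088). Its adjusted p was 0.0817 without RIP A, 0.0708 without RIP B, and 0.600 at a log2 fold change of 0.11 with length and GC trends removed. Emx1 stood at 5.57 ± 0.14 and 5.20 ± 0.84 FPKM (adjusted p = 0.769).

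Against input 5188 of 14458 genes passed, 2795 higher and 2393 lower, and unadjusted p was under 0.05 for 6813. The groups did not overlap for 71.1% of genes, against 33.3% by chance. The count was 1395 without RIP A and 1905 without RIP B, while it was 3461 and 3471 without input A or B. Both trios gave at least a 2-fold rise for 1009 genes and a 2-fold fall for 1063, where independent trios would give 211 and 259. With a mean of at least 5 FPKM these were 860 and 716.

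Genes of protein synthesis and respiration stood below input, although neither list passed against IgG (adjusted p = 0.899 and 0.282, camera, limma). Of 86 ribosomal protein genes, 60 fell and 0 rose, and adjusted over the list alone 65 fell and 1 rose. Rps15a stood at 10.3 ± 2.08 against 81.8 ± 0.22 FPKM and Rplp1 at 101 ± 22 against 574 ± 71.2 FPKM (list adjusted p = 2.6e-15, camera, limma, and adjusted p = 0.739 with an estimated correlation). Of 78 oxidative phosphorylation genes, 48 fell and 2 rose, and adjusted over the list alone 54 fell and 3 rose. The cytochrome oxidase subunit Cox8a stood at 40.3 ± 2.46 against 147 ± 2.96 FPKM (adjusted p = 6.8e-12, and adjusted p = 0.561 with an estimated correlation). Of the 16 small non-coding RNAs chosen by symbol, 13 fell and 0 rose, over all genes and adjusted over the list alone, with Rn7sk at 2100 ± 89.6 against 6139 ± 423 FPKM (adjusted p = 3.8e-08, and adjusted p = 0.739 with an estimated correlation). Of 84 small nucleolar RNAs, 39 fell and 3 rose, and adjusted over the list alone 40 fell and 3 rose, with Snord22 at 217 ± 17.7 against 857 ± 147 FPKM (adjusted p = 3.0e-06, and adjusted p = 0.739 with an estimated correlation).

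The groups that rose against IgG and also passed against input were the FMRP targets, autism genes and nuclear RNA-binding proteins, joined by ion channels. Of 31 FMRP targets 28 rose and 0 fell, over all genes and adjusted over the list alone, with the methyltransferase Kmt2d at 131 ± 2.39 against 27.2 ± 0.36 FPKM and the presynaptic scaffold Pclo at 221 ± 2.89 against 71.3 ± 1.47 FPKM (adjusted p = 9.9e-15, and adjusted p = 0.561 with an estimated correlation). Their median log2 was 1.31, and 0.54 with length and GC trends removed (adjusted p = 4.4e-06). Of 35 autism genes 20 rose and 3 fell, and adjusted over the list alone 21 rose and 3 fell, with Ankrd11 at 308 ± 2.38 against 114 ± 2.64 FPKM (adjusted p = 1.3e-05, and adjusted p = 0.561 with an estimated correlation). Of 35 nuclear RNA-binding proteins 17 rose and 2 fell, and adjusted over the list alone 22 rose and 2 fell, with Sf3b1 at 243 ± 8.17 against 86.5 ± 8.13 FPKM (adjusted p = 1.4e-05, and adjusted p = 0.739 with an estimated correlation). Of 22 voltage-gated ion channels 12 rose and 1 fell, over all genes and adjusted over the list alone, with the calcium channels Cacna1a at 88.1 ± 0.12 against 31.2 ± 5.01 FPKM and Cacna1d at 45.2 ± 0.07 against 18.1 ± 1.20 FPKM (adjusted p = 0.0046, and adjusted p = 0.691 with an estimated correlation). These were 8 of 41 lists, and 0 passed with an estimated correlation. Of the lists called against IgG, the GABA receptors, neuronal RNA-binding proteins, nuclear-retained long non-coding RNAs and histones did not pass against input. Their adjusted p was 0.0965, 0.211, 0.145 and 0.298 (camera, limma), with medians of the same sign as against IgG. Of 61 histone genes 19 rose and 12 fell against input. With length and GC trends removed the adjusted p was 0.451 for the ion channels and 0.151 for the small nucleolar RNAs, and the median of the autism genes went from 0.76 to 0.25 (adjusted p = 0.0446). The median of oxidative phosphorylation went from -0.99 to -0.63 and that of nuclear RNA-binding proteins from 0.44 to 0.69. Under quantile normalization the median was 0.21 for the nuclear RNA-binding proteins (adjusted p = 0.0200, camera) and 0.48 for the autism genes (adjusted p = 0.0104, camera).

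**Figure D2:**
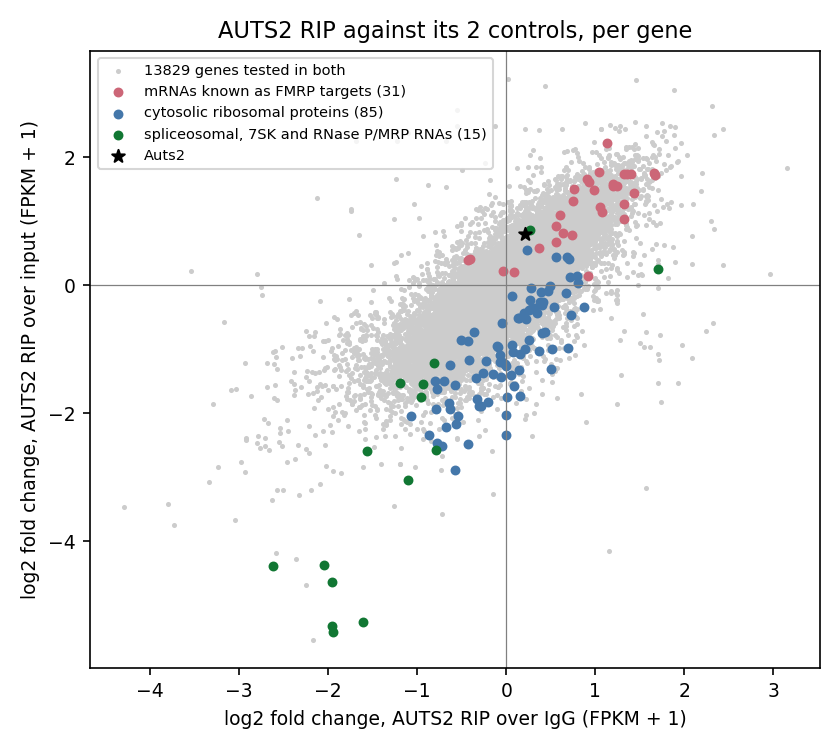
Log2 fold change of each of the 13829 genes tested in both pull-down comparisons, AUTS2 RIP over IgG on the x axis and over input on the y axis, on the log2(FPKM + 1) scale. FMRP targets (red) lie mostly above 0 on both axes, ribosomal protein genes (blue) mostly below 0 on the input axis, the small non-coding RNAs chosen by symbol, spliceosomal and 7SK RNAs among them (green), mostly below 0 on both, and the star marks Auts2.

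The genes higher against both controls numbered 1672 of 13829 tested in both, and those lower against both 941. Both comparisons use the same RIP libraries. Independent lists of these sizes would share 403 and 218 genes. Simulated unchanged groups sharing the RIP libraries called on average 1.34 and 1.2 genes higher against IgG and input, and 1.66 and 1.48 lower. They shared 0.09 genes on average in each direction. With so few calls, the simulation cannot show how much overlap shared libraries give between lists of the observed sizes. The fold changes correlated across genes (r = 0.77, with 0.47 from the simulated unchanged groups; genes are not independent replicates), with a covariance of 0.432 against 0.0387 simulated. Part of the excess may come from the shared RIP libraries, since with 2 of them no split leaves 2 for each comparison. In opposite directions 11 genes were called.

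Fold changes in the pull-down rose with transcript length. The median log2 fold change over IgG was -0.30 for the 952 genes whose most abundant transcript was under 500 bases, 0.07 for the 4865 genes of 2000 to 4000 bases and 0.40 for the 635 genes above 8000 bases, and over input these medians were -0.44, 0.06 and 0.57. Of the genes above 8000 bases 39.1% were called higher against IgG, and of those under 500 bases 7.67%. The median length was 4000.5 bases for the genes called higher against IgG, 2455 bases for those called lower and 2600 bases for all genes tested. After removal of each library's trend with length and GC content, 1498 genes were higher and 1066 lower against IgG, and 1258 and 867 of these were also called before.

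**Figure D3:**
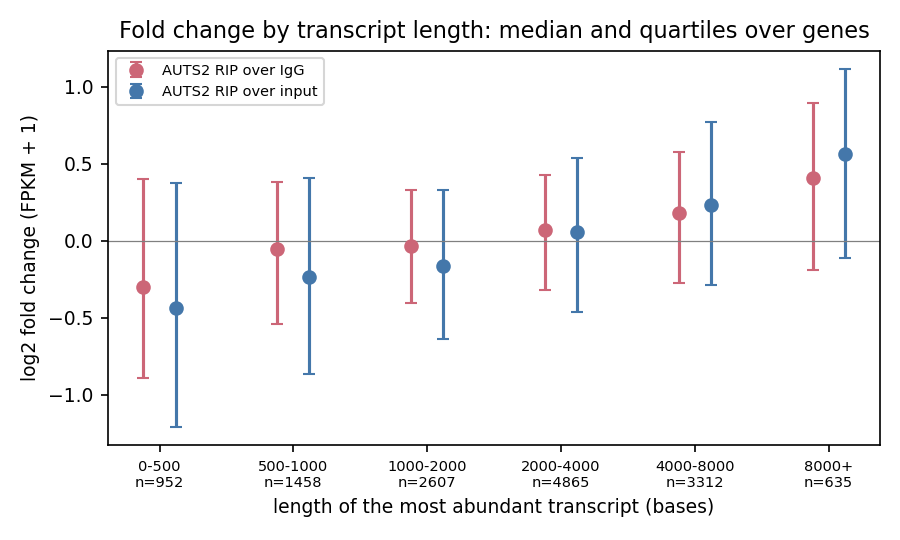
Median log2 fold change (points) with quartiles (bars) over genes in 6 classes of the length of the most abundant transcript, for AUTS2 RIP over IgG (red) and over input (blue). The medians run from -0.30 to 0.40 over IgG and from -0.44 to 0.57 over input.

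Whether transcripts in the AUTS2 complex change when Auts2 is lost was asked of the genes changed in the cKO and the genes higher in the pull-down than in IgG. Of 12175 genes tested in both sets, 1895 were higher against IgG, and 0 of the 3 genes Ndn, Auts2 and S100a10 were among them (Fisher's exact test, two-sided, p = 1; 95% interval of the odds ratio 0 to 13.1), too few genes to show a difference. Against input 1 of the 3, Auts2, was among the 2645 higher genes of 12232. Of the 956 genes at an unadjusted p under 0.05 in the cKO, 134 were pulled down. That is 14% against 15.6% of all genes, an odds ratio of 0.876 (95% interval 0.719 to 1.06, exact p = 0.178). The directions differed: 48 of 547 higher genes were pulled down (8.78%, odds ratio 0.509, 95% interval 0.369 to 0.689) and 86 of 409 lower genes (21.0%, odds ratio 1.47, 95% interval 1.14 to 1.88). Without cKO 1 these were 98 of 634 (15.5%, odds ratio 0.992, 95% interval 0.787 to 1.24) and 63 of 385 (16.4%, odds ratio 1.06, 95% interval 0.795 to 1.40), so the difference rests on cKO 1. These intervals take genes as independent. As a set, the pulled-down genes had a median log2 fold change in the cKO of -0.027, against 0.0053 for the others, a difference of -0.032. Camera gave p = 0.0107 with the preset correlation, p = 0.289 with an estimated correlation, and p = 0.0836 at a difference of -0.021 when length and GC trends were removed from the RIP fit. This set difference was not tested without cKO 1, so whether it also rests on that library is unknown.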

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

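The tests of cKO 1, of the Xist covariate, of DNA near the engineered alleles and of splits without Auts2 were chosen after the results were seen, while the predictions for transcript length and for splits with all genes were written before those tests were run.

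In 13 of 206 groups of 4 frontal cortex libraries, a single library stood apart by a wide gap (Dixon's test), where chance gives about 5% of groups. Pcgf5 stood at 1.14 FPKM in wild type 3 (others 1.49 to 1.53), Ep300 at 15.6 in wild type 4 (18.7 to 19.3), Aurka at 2.53 in wild type 4 (3.34 to 3.49) and Pcdhb9 at 3.66 in wild type 2 (3.83 to 3.85). Pspc1 stood at 43.5 FPKM in cKO 2 (others 45.5 to 45.9), Elavl4 at 37.5 in cKO 3 (33.2 to 33.9) and Cdh5 at 2.28 in cKO 3 (2.79 to 2.89). Library cKO 1 accounted for 5 of them: Abcc9 at 2.31 FPKM (2.75 to 2.83), Npas4 at 1.87 (1.37 to 1.41), the chaperone gene Hspa8 at 402 (491 to 496), Spen at 11 (18.5 to 19.2) and the ribosomal protein gene Rpl3 at 349 (291 to 299). The mean log2 level of nuclear-retained long non-coding RNAs was 4.64 in cKO 4 and 5.11 to 5.17 in the other cKO libraries.

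Transcript length and pull-down rose together. Recovery of long RNAs by any immunoprecipitation may account for part of this. The length slope of IgG over input was 0.393 of that of AUTS2 RIP over input in trio A and 0.519 in trio B. The spread over resampled genes was 0.326 to 0.591. The remainder could come from the antibody or from library differences, and these cannot be told apart with 2 trios and a single antibody. GC content as the whole cause of the slope over IgG is argued against, as the slope with GC in the model was 1.17 of that without. Short and non-coding RNAs alone are also argued against, as the slope among protein-coding genes above 1 kb was 1.15 of that over all genes.

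Gene list shifts in the cKO were set only against library cKO 1 and the unequal Xist states, each as the share of the median that was left. For ribosomal protein genes -0.472 was left without cKO 1 and 0.249 with the Xist covariate, in line with that shift resting on those libraries. For oxidative phosphorylation 0.513 was left without cKO 1 (0.360 to 0.575), so a part may come from cKO 1 and the rest stays open, and 0.929 with Xist, which argues against Xist state. The Zfp genes kept 0.98 and 1.65, and intermediate progenitor genes 2.01 and 1.68, which argues against either as their cause. Other single libraries moved these too, with medians of -0.04 for the Zfp genes without cKO 4 (-0.09 with all) and -0.05 for intermediate progenitors without cKO 3 (-0.11 with all). The likeness of wild type 1 and 2 (r = 0.993, and at most 0.987 with the other libraries) was not tested as a cause. With an estimated correlation 0 lists passed, so variation between libraries may also account for the remaining shifts. Whether that, loss of Auts2, Cre expression or strain lies behind them stays open, as these libraries cannot separate these.

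The 3 genes called in the cKO were set against chance, Xist state and linked DNA. Of the 35 splits of the 8 libraries into 4 and 4, the real split alone gave 3 genes (1 of 35) and the highest other 2, but Auts2 is the deleted gene. Without Auts2 the real split gave 2 genes and so did a single other split (2 of 35), while the remaining splits gave at most 1. That split parts the libraries exactly by Xist state, a known difference between them, so it is no clean measure of chance, and the count of genes other than Auts2 stays open. With the Xist covariate Ndn kept 0.993 of its fold change (adjusted p = 0.025, limma) and S100a10 1.03 (adjusted p = 0.103), which argues against Xist state as the cause of either fold. Variants linked to the engineered alleles may add changed genes: 3 of 572 genes within 20 Mb of Auts2 or Emx1 (Cyp26b1, Mmab and Mvk, of which Mmab and Mvk are neighbours) had p under 0.001 against 19 of 12212 elsewhere, an odds ratio of 3.38 (95% interval 0.639 to 11.5, exact p = 0.073), too few to decide. Auts2 and Emx1 themselves were left out of that test, and Ndn and S100a10 lie on other chromosomes. For Ndn and S100a10, Cre expression and strain differences elsewhere in the genome cannot be told apart from loss of Auts2. Libraries with Cre alone or floxed alleles alone were not analysed.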

How the results depend on the processing

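The Xist covariate, the removal of length and GC trends, the removal of genes listed at 0 in some libraries, the rescalings of the list tests and the estimated correlation for the pulled-down genes were chosen after the results were seen; all other settings here were set before. The 3 called cKO genes became 1 with no filter on low values, without trend and robust settings, with the Xist covariate and on transcripts, 5 at a threshold of 0.1, and 1 to 3 with a library left out. Against IgG the 3406 calls became 1876 without trend and robust settings, 0 on transcripts (limma, lowest adjusted p = 0.0528, 7158 at unadjusted p under 0.05) and 0 to 1806 with a library left out. Against input the 5188 became 2133 on transcripts and 1395 to 3471 with a library left out. A transcript fit tests more units; for the other settings the cause was not tested. Called lists (6, 9 and 8) became 0 in each comparison with an estimated correlation, and 4 to 12, 9 to 12 and 8 to 9 with a library left out. With a mean of at least 5 FPKM the adjusted p was 0.0683 for intermediate progenitors and 0.0643 for AUTS2 and its partners (camera, limma). The median of the ribosomal protein list in the cKO reversed to -0.024 without cKO 1 and ran from there to 0.0874 with each library left out (0.05 with all). At a pseudocount of 5, which shrinks low genes, 180 and 532 genes were 2-fold higher in both trios against IgG and input, from 439 and 1009, and 156 and 369 lower, from 721 and 1063. By that 2-fold definition 317 genes were higher against both controls, from 1672. The overlap with the cKO was 134 genes at unadjusted p. The set difference of pulled-down genes in the cKO was -0.021 (p = 0.0836) with trends removed and -0.032 (p = 0.289) with an estimated correlation. Leaving a single library in a group assumes that it varies like the other group.

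With a replicate block by trio 3455 genes were called against IgG and 5222 against input, and it moved no count in those comparisons by over 1.5 times. The labels do not say whether frontal cortex numbers pair animals. Same-numbered deviations correlated at r = 0.176, 0.0173, -0.0394 and 0.0659, and different-numbered ones at -0.148 to 0.162, which does not settle it. A block by these numbers gave 4 calls, 2 of them among the 3, without S100a10 (adjusted p = 0.0503, limma). No called gene or list of those named was called in the opposite direction under another setting, apart from the ribosomal list. Among named genes 18, 247 and 116 results in the cKO, IgG and input comparisons lost their call under some setting and 3, 4 and 7 gained it, and for lists 15, 13 and 10 lost it. Depth is unknown.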

Other observations

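The tests of sterol and imprinted genes were chosen after the results were seen.

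Genes of cholesterol synthesis stood together in the cKO. Mvk, Mmab and Insig1 were noticed among the genes with small unadjusted p, and a list of sterol pathway genes was then assembled. Mvk and Mmab are neighbours within 20 Mb of Auts2. All 24 tested members had a positive fold change, with a median log2 of 0.31, and 0 passed over all genes. The synthase gene Hmgcs1 stood at 268 ± 31.3 FPKM in the cKO and 212 ± 32.7 FPKM in wild type, and the isomerase gene Idi1 at 13.4 ± 1.92 and 8.97 ± 2.90 FPKM (4 libraries each). Srebf2, which encodes the transcription factor of the pathway, stood at 48.6 ± 5.49 and 46.5 ± 4.77 FPKM. A coordinated rise of the pathway may underlie this: without the 3 noticed genes 21 of 21 stayed positive with a median of 0.28. The camera test of these 21 with an estimated correlation gave p = 0.0667, so the hypothesis stays open. The median was 0.31 without library cKO 1 and 0.33 with the Xist covariate, and camera with an estimated correlation gave p = 0.0819 and 0.128.

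Ndn, Rian, Meg3 and Airn are imprinted, and a rise of imprinted genes as a class was a candidate explanation. It is argued against: the 34 other imprinted genes tested had a median log2 of -0.023, with 16 positive (camera p = 0.834 with an estimated correlation). Magel2, which lies beside Ndn and is also expressed from the paternal allele, stood at 1.82 ± 0.37 FPKM in the cKO and 2.04 ± 0.38 FPKM in wild type. Other paternally expressed genes of that region differed in direction. Snrpn stood at 148 ± 5.83 and 132 ± 8.33 FPKM, Mkrn3 at 6.32 ± 0.68 and 5.75 ± 0.33 FPKM, and Peg12 at 1.06 ± 0.14 and 1.19 ± 0.36 FPKM. None of these neighbours passed over all genes.

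Within lists that did not pass against IgG, single members moved in opposite directions. Among astrocyte genes, Sparcl1 stood at 747 ± 24.1 FPKM in the RIP and 359 ± 53.0 FPKM in the IgG libraries, while Slc1a2 stood at 32.9 ± 0.10 and 50.0 ± 2.92 FPKM, and both passed (adjusted p = 0.0039 and 0.017, limma). Among early neuronal genes Map1b rose (1280 ± 73.7 against 844 ± 94.0 FPKM) and Dcx fell (85.5 ± 8.12 against 176 ± 2.77 FPKM). Fbrsl1, a paralogue of Auts2, rose as well, at 89.5 ± 3.31 against 52.0 ± 2.70 FPKM (adjusted p = 0.0060).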
